A study of Danio rerio with 6 samples.

How the data were processed

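Small RNA was extracted with a column kit from pools of 50 zebrafish embryos of the AB strain at 30% epiboly, 4.5 hours after fertilisation, and sequenced on Illumina libraries, per the labels' protocols. The 6 libraries formed 2 groups of 3, wild type and maternal-zygotic dgcr8 mutants (MZdgcr8), taken from the genotype labels. Dgcr8 is the RNA-binding partner of Drosha in the Microprocessor, which cuts primary miRNA transcripts into hairpin precursors. The labels do not say that the libraries came from separate clutches. The p-values below of tests between libraries thus measure only the spread between these samples, which may be technical.

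The authors deposited 1 table of 1026 rows, each a mature sequence at a hairpin, with a raw and a normalized value per library. Per the file headers, reads were mapped to miRBase precursors of zebrafish and then of selected other species, the precursors were mapped to the genome, and reads outside miRBase that lay in genome sequence able to fold into a hairpin were kept as predicted miRNAs. A further header group held reads that matched a mature miRNA of another species and did not map to the zebrafish genome. Suffixes on a name mark variants with bases added, removed or substituted against the reference miRNA. The aligner, the miRBase release and the genome build were not given in the sources used here, so coordinates are quoted as the table lists them, and they are those of the hairpin. The raw values were deposited by the authors as estimated counts, because reads of a sequence with several hairpin loci were divided over its rows. Summed over the rows of a sequence, 92.3% of the non-zero sums were whole within 0.01. The authors' normalized values, a signal on a linear scale, equalled the raw values divided by 1 constant factor per library, from 0.349 to 2.20; how the factor was set was not given in the sources used here.

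The rows of each of the 827 distinct mature sequences were summed, and the sums were rounded to whole reads, since the test had been chosen for whole counts. In all, 148 sequences lay in several rows. The 827 sequences were 241 with a zebrafish name, 205 with the name of another species and 381 predicted miRNAs, and 103 of the 827 had not mapped to the genome. A further 6 lines of the table were empty and were not analysed here. Members of a family that differ by a few bases can share reads, so values of single miR-430, let-7 or miR-92 members are less certain than the family totals. Among sequences with 1 row, 38 of 1490 non-zero values were below 5 reads, so a listed 0 was treated as below 5 reads per library, and a fold against a group at 0 was computed against that floor and given as a lower bound. Both the values and the floor were TMM-scaled (below), so each bound holds only under that scaling.

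Library totals ranged from 5791 to 6035911 reads. Confidence intervals of shares are 95% Wilson intervals and cover counting error only, since the reads carry no molecular identifiers. Pairs of libraries within a group differed by far more than counting error (the smallest chi-square was 11510 on 280 degrees of freedom), so no library was treated as a duplicate.

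Before the data were examined, the following were fixed: the tests, 16 lists of miRNAs, the alternative settings and the rule for named miRNAs. Differences were tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr with its default minimum of 10 reads and total of 15) in R 4.3.3, at a Benjamini-Hochberg adjusted p under 0.05, without a replicate block. The filter left 173 features. The test gives no SE. The SE printed with an edgeR log2 fold change is that change, without its sign, divided by the square root of the F statistic. It is an approximation, least certain for features near 0 reads in 1 group. Abundances are given as TMM-scaled reads, that is, reads divided by the effective library size and multiplied by the mean effective size. The TMM factors ranged from 0.0453 to 0.318 in wild type and from 3.59 to 13.4 in MZdgcr8. No spike-in was described, so a change in the amount of RNA per embryo cannot be told from these values. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, which left 13 lists; camera with an estimated correlation and fry were run beside it. Camera compares the members of a list with all other features, whereas fry tests whether they change on balance in 1 direction. The 3 annotation classes had been fixed for the same test, and the class not mapped to the genome was added after the data were seen. Shares, totals and numbers of features were compared with exact permutation tests on the difference of means, two-sided, for which 3 against 3 gives no p under 0.1. Arms of a hairpin were compared with an exact sign test.

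The rule named 56 features: the 10 with the highest mean in each group, the 6 largest falls and rises among called features without overlap between groups and with at least the median abundance of tested features, up to 3 most abundant members of each list, and each tested member of the list of miRNAs that bypass the Microprocessor elsewhere. Features named outside this rule are said to be so.

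The alternatives were 5 other scalings, DESeq2 1.42.0, limma-voom, limma on the authors' normalized values with pseudocounts of 0.5, 1 and 5, other filters, other ways to combine rows, a fit with a replicate block, and leaving out each library. A further 4 fits and a stricter pairing of arms were added after the data were seen. Both groups carry the numbers 1 to 3 in their titles. Deviations from the group mean correlated by 0.54, 0.37 and 0.681 between libraries of the same number, all above the limit of 0.1. By that limit the numbers were taken to pair the libraries, though the labels name no pairing. Wild-type library 2 and MZdgcr8 library 1 correlated by 0.594, and wild-type library 1 and MZdgcr8 library 2 by 0.4. The number 3 libraries correlated with those of other numbers by -0.405 to -0.653. Deviations sum to 0 within a group, so the values of libraries 1 and 2 depend on those of library 3. The correlations thus set library 3 apart and do not show that libraries 1 and 2 are paired by number. Libraries 1 and 2 of both groups were therefore also analysed without library 3.

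The tests were checked on simulated counts drawn from the wild-type means and the TMM effective library sizes, with 200 changed features. These sizes exceeded the real totals of the mutant libraries, at 77639 against 5791 reads in MZdgcr8 library 3. Depth was not varied. At the dispersion of the data (2.13), edgeR called 75% of 28 tested features with a 512-fold change, 0 of 18 with a 32-fold change and 1 of 157 unchanged features. At a dispersion of 0.1, it called all 34 features with a 32-fold change. Camera called a simulated set lowered 16-fold and did not call an unchanged set. Python with pandas, numpy, scipy and matplotlib was used for the other steps.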

Results

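Small RNA sequencing was compared between wild-type zebrafish embryos and embryos lacking both maternal and zygotic dgcr8, a gene required to process most miRNA precursors. Each group had 3 libraries of 50 embryos, taken at 4.5 hours after fertilisation. The comparison asked which miRNAs of the early embryo depend on Dgcr8. Wild-type libraries 1, 2 and 3 held 1556391, 2020760 and 6035911 reads in the table, and MZdgcr8 libraries 1, 2 and 3 held 30743, 83057 and 5791. Mean totals differed 80.4-fold (44.9-fold without wild-type library 3 and 175-fold without MZdgcr8 library 2), with no overlap between groups (exact permutation p = 0.1, two-sided, n = 3 per group, the smallest p this design allows). The transcript of dgcr8 itself is not measured in a miRNA table, so the mutation was not checked here.

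Shares of a library, here and below, are of its reads assigned to known or predicted miRNAs, since other small RNA reads were not given in the sources used here. The miR-430 family, which is transcribed at the onset of zygotic transcription and clears maternal mRNAs, made up nearly all such reads in wild type and a small part in the mutants. It held 94.9% ± 3.90 of the reads in wild type (SD, n = 3) and 5.65% ± 6.83 in MZdgcr8 (SD, n = 3), with no overlap between groups (exact permutation p = 0.1, two-sided, the smallest possible; adjusted p = 0.178 over 16 lists). The wild-type shares were 92.5% (95% Wilson interval 92.4 to 92.5%), 92.9% (92.9 to 93.0%) and 99.4% (99.4 to 99.4%). The MZdgcr8 shares were 1.96% (1.81 to 2.12%), 1.46% (1.38 to 1.54%) and 13.5% (12.7 to 14.4%). The gap was present in libraries 1 and 2 alone, where the shares differed by -90.98 percentage points, and between the number 3 libraries, where 1 library stood against 1 and no test was possible. In raw reads, the MZdgcr8 libraries kept 603, 1211 and 784 reads of the family. Predicted hairpin sequences held 50.4% ± 0.738 of the mutant libraries against 0.446% ± 0.333 in wild type (SD, n = 3), and 1 sequence, PC-5p-27_64448, made up 45.0% and 46.1% of MZdgcr8 libraries 1 and 2 and was at 0 in library 3. The other zebrafish miRNA names held 29.8 to 36.5% of the mutant libraries against 0.475 to 6.29% in wild type, and names of other species held 6.99 to 16.8% against 0.0255 to 0.822%.

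**Figure D1:**
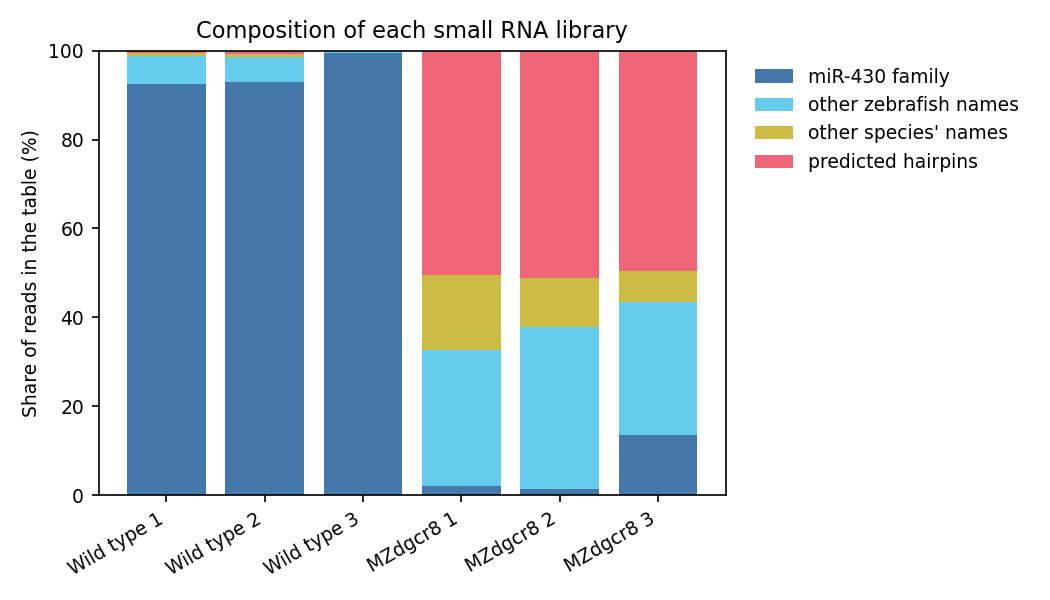
Stacked bars give shares (%) of each library's reads assigned to known or predicted miRNAs, for 3 wild-type and 3 MZdgcr8 libraries. The parts are the miR-430 family, other zebrafish miRNA names, names of other species and predicted hairpins. The miR-430 share is 92.5 to 99.4% in wild type and 1.46 to 13.5% in MZdgcr8.

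In the test across features, 11 of 173 were lower in MZdgcr8 and 0 were higher (edgeR, adjusted p under 0.05). Of the 11, 7 were miR-430 sequences, 3 were from miR-92a hairpins and 1 was miR-15c, and the groups did not overlap in any of them. The 3 main miR-430 mature sequences lie in a cluster on chromosome 4. MiR-430a-3p (TAAGTGCTATTTGTTGGGGTAG, first listed hairpin at 28740307 to 28740388) had a log2 fold change of -10.86 (SE 1.87, adjusted p = 0.0233, edgeR), from 662068 ± 507374 to 357 ± 228 scaled reads (SD, n = 3). MiR-430b-3p (AAAGTGCTATCAAGTTGGGGTAG, first listed hairpin at 28739576 to 28739656) had a log2 fold change of -10.60 (SE 2.29, adjusted p = 0.0275, edgeR). MiR-430c-3p (TAAGTGCTTCTCTTTGGGGTAG, 28738728 to 28738800) fell from 103104 to 113623 raw reads per wild-type library to 14, 0 and 0 in the mutants (log2 fold change -13.00, SE 2.70). The opposite arms miR-430b-5p, miR-430a-5p and miR-430a-12-5p had log2 fold changes of -9.26, -9.58 and -8.18, and a variant of miR-430c-5p was at 0 in all 3 mutant libraries, at least 82.8-fold lower. This bound and those below hold under TMM scaling only and would be smaller with library totals.

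Outside miR-430, the passenger strand miR-92a-5p (hairpin on chromosome 1, 3297367 to 3297451) held 2173, 3090 and 2006 raw reads in wild type and 0 in each mutant library, at least 145-fold lower. MiR-92a-2-5p (chromosome 9, 53896683 to 53896777) was at least 64.7-fold lower, again with 0 in each mutant library. The miR-92a-3p variant with 1 added base fell by 5.02 on the log2 scale (SE 1.24, adjusted p = 0.0472, edgeR). MiR-15c held 1939, 2180 and 127 raw reads in wild type and 0, 5 and 0 in MZdgcr8. Its fitted fall was 8.53 (SE 2.02, adjusted p = 0.0401, edgeR), a size not measured because the mutant values lay at or below the floor of 5 reads.

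The count of lower features depended on the libraries, the scaling and the pairing. With the replicate number as a block, 4 features were lower (miR-430a-3p, miR-430b-3p, miR-430a-5p and miR-430a-12-5p), and leaving out wild-type library 3, MZdgcr8 library 1 or MZdgcr8 library 2 gave 3, 0 and 0. In libraries 1 and 2 alone, 79 features were lower and 16 were higher, while scaling to the library total gave 0 lower and 2 higher, or 9 lower and 87 higher with the replicate block, and moved the median log2 fold change of all tested features from 0.46 to 4.45. Reads of miR-430 made up 92.5 to 99.4% of the totals in wild type and 1.46 to 13.5% in MZdgcr8. Division by the total thus raised the log2 fold changes of all features together. With miR-430 left out of the total, the median was 0.26. Of features higher in MZdgcr8, 2 had an unadjusted p under 0.05 in edgeR (miR-133a-3p and the predicted PC-3p-81730_20, the latter chosen after its values were seen). DESeq2 called neither of them and called 2 other predicted features higher, PC-5p-14871_107 and PC-5p-4589_302, at 8.92 and 9.64. Both are named here after their values were seen. In limma-voom, 1 feature was called higher. No overlap between groups in TMM-scaled reads was seen for 34 features lower and 15 higher among the 173, where chance gives 10% for both directions together. The division between directions depends on the scaling.

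**Figure D2:**
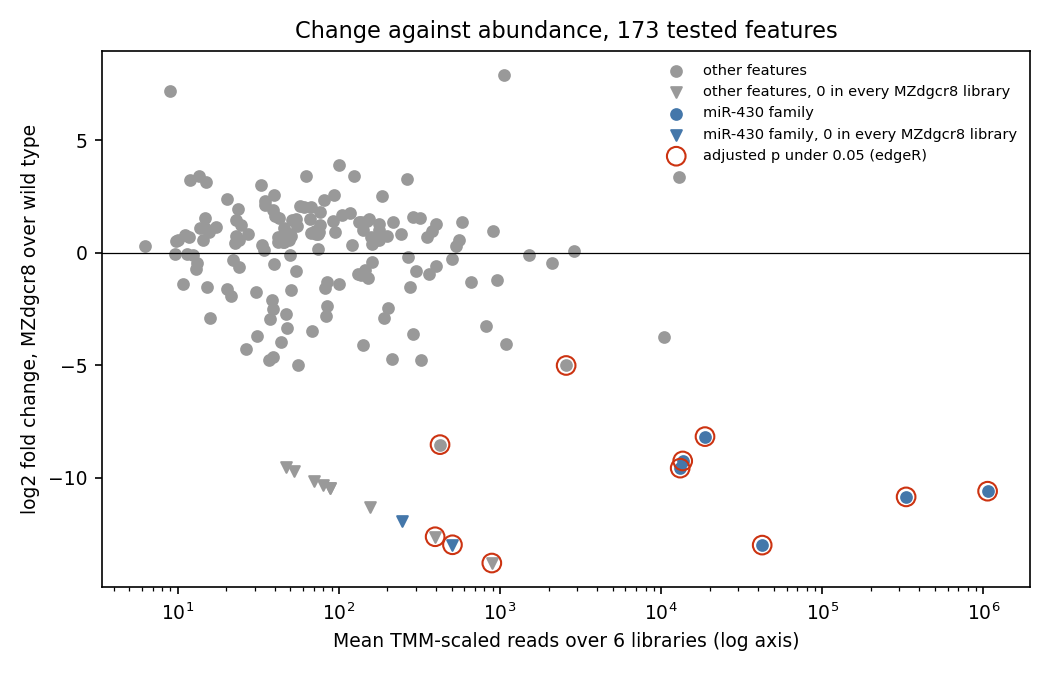
Each point is 1 of 173 tested features, with its mean TMM-scaled reads over 6 libraries (log axis) against its log2 fold change in MZdgcr8 over wild type. Red circles mark the 11 features called by edgeR, all lower, and triangles mark features at 0 in every MZdgcr8 library, whose fitted fold changes are not measured sizes.

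Lists of related miRNAs were compared next. The miR-430 list was lower as a whole (camera adjusted p = 2.62e-09, or 0.0287 with an estimated correlation). Of 8 tested members 7 were called lower, 8 when adjusted over the list alone. All 8 lay below 0, without overlap between groups. Its median log2 fold change was -10.73, or -9.42 with members at 0 set to their bound. Its median lay below 0 under each of the 6 scalings, at -5.46 when scaled to the library total. The miR-17/92 clusters, expressed in proliferating cells, were lower by camera (adjusted p = 8.06e-04; adjusted p = 0.324 with an estimated correlation). Of 12 tested members 3 were called lower, all from miR-92a hairpins, and 5 when adjusted over the list alone. In all, 10 of the 12 lay below 0, and 8 were lower without overlap between groups. The median log2 fold change was -3.44, or -3.18 at the bounds, and turned to 1.01 when scaled to the library total. It ran from -7.84 to -3.87 when 1 library was left out, lowest without MZdgcr8 library 2. In that fit 20 members were tested, and MZdgcr8 libraries 1 and 3 held reads of 9 and 4 members. Some members were thus at 0 in both, with fitted sizes that are not measured. MiR-92a-3p, its most abundant member, had 19498 ± 10756 scaled reads in wild type and 1459 ± 1339 in MZdgcr8 (SD, n = 3; log2 fold change -3.74, SE 1.46, adjusted p = 0.212, edgeR). As a share of the library, the clusters were not separated, at 2.46% ± 1.93 in wild type and 2.91% ± 1.96 in MZdgcr8 (SD, n = 3; exact permutation p = 0.7).

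In the miR-15/16 family, 1 of 7 tested members was called lower, 2 when adjusted over the list alone. Of the 7, 5 lay below 0 and 3 were lower without overlap between groups. The list did not pass (camera adjusted p = 0.317). Its median log2 fold change was -2.73, and 2.33 when scaled to the library total. The median was 2.26 and 1.61 without wild-type library 1 or 2, when 3 members were tested, and -7.61 without MZdgcr8 library 2. In that last fit 10 members were tested, and MZdgcr8 libraries 1 and 3 held reads of 3 and 1 members. Its median is thus a fitted size over members at 0, not a measured one. MiR-16b had 335 ± 53.1 scaled reads in wild type and 44.9 ± 39.4 in MZdgcr8 (SD, n = 3; log2 fold change -2.89, SE 1.65). The let-7 family, which rises late in development, had a median log2 fold change of 1.06 over 10 tested members and none called (camera adjusted p = 0.0695; 0.0342 with the replicate block, 0.0469 without MZdgcr8 library 2 and 0.0344 without MZdgcr8 library 3; adjusted p = 0.914 with an estimated correlation). With library totals and the replicate block together, all 10 were called higher, among them let-7a at 6.15 and let-7b at 4.56. Over all features, 87 of 173 were higher in that fit, with a median log2 fold change of 4.12. In libraries 1 and 2 alone, let-7e, chosen after its values were seen, was called higher at 6.58. The let-7 median was 0.0036 without MZdgcr8 library 2 and was 0.17 without wild-type library 3 and -0.10 without a filter. It turned to -0.26 without scaling and to -1.68 when scaled to predicted hairpins. Of the predicted reads behind that scaling, PC-5p-27_64448 held 13832 of 15537 and 38281 of 42467 in MZdgcr8 libraries 1 and 2. It held 4377 of 9187 and 7998 of 13798 in wild-type libraries 1 and 2, and 0 in both number 3 libraries. Values scaled to predicted hairpins, here and below, thus rest heavily on 1 sequence in libraries 1 and 2. Let-7a had 232 ± 164 scaled reads in wild type and 567 ± 434 in MZdgcr8 (SD, n = 3). In raw reads, the let-7 family held 1681, 2523 and 101 in wild type and 1092, 2455 and 82 in MZdgcr8.

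The remaining lists of abundant miRNAs did not pass, and their members were called in some other fits only. With library totals and the replicate block together, 5 of 11 tested members of the miR-10 group were higher. So were 20 of 30 widely expressed miRNAs and 5 of 5 mesenchymal miRNAs. Among them were miR-100-5p, miR-21 and miR-143 at 3.44, 6.11 and 6.22. Over all features, 87 of 173 were higher in that fit, with a median log2 fold change of 4.12, and miR-100-5p lay below that median. In libraries 1 and 2 alone, miR-22a-3p and miR-99 were lower, at -4.63 and -2.20. For the group of miR-10, miR-99, miR-100 and miR-125, none of 11 tested members was called and the list did not pass (camera adjusted p = 0.791, upward), with a median log2 fold change of 0.09 and a mean of -0.23. MiR-100-5p had a log2 fold change of -0.45 (SE 1.52) and miR-125b-5p one of 0.09 (SE 2.03). Widely expressed miRNAs had a median log2 fold change of 0.63 and a mean of -0.31, with none of 30 called (camera adjusted p = 0.645). MiR-21 had 618 ± 355 scaled reads in wild type and 1196 ± 371 in MZdgcr8 (SD, n = 3), while miR-22a-3p had 2063 ± 480 and 124 ± 45.2, without overlap and with an adjusted p of 0.0589 in edgeR. The mesenchymal list (miR-143, miR-145, miR-199 and miR-214) had a median of 1.34 with none of 5 called (camera adjusted p = 0.598). MiR-202-5p and miR-34c-3p, reported in ovary or as maternal elsewhere, were sparse. MiR-202-5p held 46, 102 and 0 raw reads in wild type and 32, 145 and 0 in MZdgcr8, and miR-34c-3p held 80, 114 and 0 in wild type and 0 in each MZdgcr8 library. Their list, the list of miR-130, miR-301 and miR-454 and the muscle list had 1 tested member each and were not tested as lists. The medians of the miR-10 group, the widely expressed miRNAs and the mesenchymal list were all positive when scaled to the library total, from 4.07 to 5.66, and all negative when scaled to predicted hairpins, from -2.12 to -1.05. When 1 library was left out, they ran from -1.40 to -0.43, from -1.66 to 0.68 and from -0.26 to 1.09, respectively, each lowest without a mutant library.

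**Figure D3:**
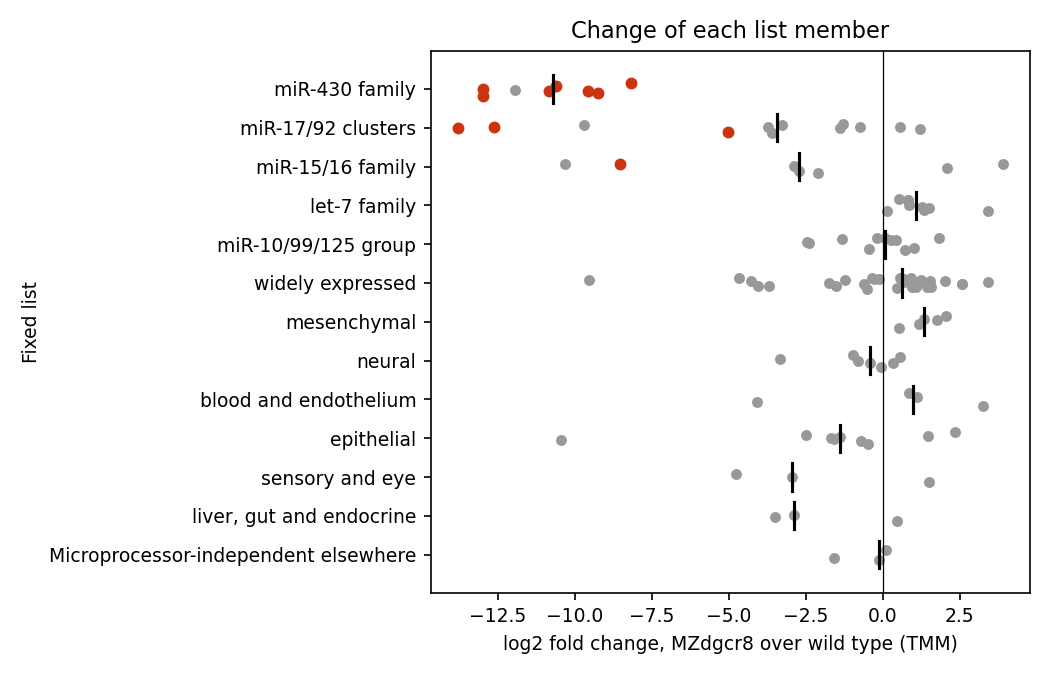
Points give the log2 fold change (MZdgcr8 over wild type, TMM) of each tested member of 13 lists, with black bars for list medians and red points for members called by edgeR. The miR-430 median is -10.73 and the miR-17/92 median is -3.44; under scaling to the library total they are -5.46 and 1.01.

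Lists of markers of differentiated cell types held 0.00198 to 0.0942% of the wild-type libraries on average, beside the large share of miR-430, and were uneven among the mutant libraries. None of the neural, blood, epithelial, sensory or endodermal lists passed (camera adjusted p of 0.791, 0.844, 0.664, 0.645 and 0.598). Their median log2 fold changes were -0.42, 0.98, -1.40, -2.94 and -2.90; scaled to the library total, all 5 were positive, from 1.46 to 4.75, and scaled to predicted hairpins all 5 were negative, from -5.21 to -0.57. When 1 library was left out, the neural median ran from -3.83 to -0.58, the blood median from -0.74 to 2.05, the epithelial from -2.72 to -1.27, the sensory from -4.70 to -0.88 and the endodermal from -3.70 to -1.09 in the 5 fits that tested it. Among members, miR-200a-5p of the epithelial miR-200 family was at 0 in each mutant library, at least 14.3-fold lower (edgeR adjusted p = 0.0549), and miR-204-5p, known from the eye, had 621 ± 307 scaled reads in wild type and 22.3 ± 24.0 in MZdgcr8 (SD, n = 3; log2 fold change -4.77, SE 1.69, adjusted p = 0.151, edgeR). The muscle miRNAs miR-133a-3p, miR-1 and miR-206-3p held 5898, 332 and 252 raw reads in MZdgcr8 library 2 and 13, 0 and 0 in library 1, with 0 in library 3. The muscle list took 8.24% of MZdgcr8 library 2 (95% Wilson interval 8.06 to 8.43%) and 0.0423% of library 1. MiR-451, an erythroid miRNA, held 1293 reads in MZdgcr8 library 2, 22 in library 1 and 0 in library 3. MiR-192, known from gut and liver, held 1483 reads in wild-type library 3, 265 in MZdgcr8 library 3 and 0 in the 4 other libraries.

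The annotation classes were compared with each other. Sequences with zebrafish names were lower than the rest, with 11 of 93 called and a median log2 fold change of -0.97 (camera adjusted p = 1.36e-06; adjusted p = 0.236 with an estimated correlation). The 11 were those named above, most of them miR-430 sequences. Over the 86 zebrafish names outside miR-430 the median was -0.55, and they were not tested as a class. Names of other species were higher than the rest, with a median of 0.73 and 0 of 58 called (camera adjusted p = 2.93e-04; 0.48 with an estimated correlation, and 0.54 without wild-type library 3). Predicted hairpins were also higher than the rest, with a median of 1.65 and 0 of 22 called (camera adjusted p = 0.0242; 0.236 with an estimated correlation). Each class was compared with the others, miR-430 included, so these 3 results are not independent of each other or of the fall of miR-430. The class medians depended on the scaling, at 3.40, 4.60 and 5.88 with library totals and -4.14, -1.67 and -0.71 when scaled to predicted hairpins. They also depended on single libraries: the median of zebrafish names was -3.00, -4.91 and -2.61 without MZdgcr8 library 1, 2 or 3. That of predicted hairpins was 0.22 without MZdgcr8 library 1 and -1.03 without MZdgcr8 library 2, and that of other species was -0.40, -0.16 and -0.07 without MZdgcr8 library 1, MZdgcr8 library 2 or wild-type library 3. Among predicted hairpins, PC-5p-27_64448 (GTGTACAACTCTTAGCGT, chromosome 16, 4630636 to 4630734) was the most abundant feature in MZdgcr8 libraries 1 and 2, at 13832 and 38281 raw reads, against 4377 and 7998 in wild-type libraries 1 and 2 and 0 in both number 3 libraries. Sequences that had not mapped to the zebrafish genome made up 0.203% ± 0.176 of wild-type reads and 6.23% ± 1.92 of MZdgcr8 reads (SD, n = 3; exact permutation p = 0.1). As a class they were higher than the rest, with 0 of 30 called and a median of 0.79 that was -1.66 when scaled to predicted hairpins and -0.19 without MZdgcr8 library 1 (camera adjusted p = 0.00618; 0.48 with an estimated correlation, and 0.54 without wild-type library 3). Their raw reads were 4045, 6955 and 370 in wild type and 2556, 4835 and 263 in MZdgcr8.

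Some miRNA names in the table denote RNAs that bypass the Microprocessor, or fragments of other structured RNAs, in other vertebrates. None of the 3 tested was called and their list did not pass (camera adjusted p = 0.664, upward), with a median of -0.12. The median was 3.80 with library totals, -2.47 when scaled to predicted hairpins, and -1.72 to -0.17 when 1 library was left out. MiR-1260a had 1574 ± 1323 scaled reads in wild type and 1445 ± 1477 in MZdgcr8 (SD, n = 3; log2 fold change -0.12, SE 1.54). MiR-484 and miR-1260b had log2 fold changes of 0.11 (SE 2.10) and -1.60 (SE 2.05). MiR-484, which had no listed position in the zebrafish genome, was called higher with library totals and the replicate block together (4.02, edgeR adjusted p = 0.0246). Over all features, 87 of 173 were higher in that fit, with a median of 4.12, so miR-484 lay below the median. MiR-1260b was called lower in libraries 1 and 2 alone (-2.54, edgeR adjusted p = 0.0315).

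Both arms were tested for 16 pairs that the table lists at 1 hairpin. MiR-430a-3p stood in 2 of them, and 1 joined the miR-16b sequence, listed at the miR-16c hairpin as a variant, to miR-16c-3p. The median difference in log2 fold change, 5p minus 3p, was 0.15, and the 5p arm was the lower one in 7 of 16 (exact sign test p = 0.804, two-sided). With 1 pair per 3p sequence and the same name on both arms, 14 pairs were left, with a median of -0.11 and the 5p arm lower in 7 (exact sign test p = 1, two-sided). The 5p arms of both miR-92a hairpins differed from their 3p arms by -10.19 and -8.89, though these 5p values were 0 in each mutant library and the sizes are fitted. The number of features detected was 392 ± 98.7 in wild type and 253 ± 133 in MZdgcr8 (SD, n = 3; exact permutation p = 0.2, two-sided). It ranked as the reads outside the miR-430 family did in all 6 libraries. Those reads were 117286, 143132 and 34118 in wild-type libraries 1 to 3, with 441, 456 and 278 features, and 30140, 81846 and 5007 in MZdgcr8 libraries 1 to 3, with 227, 397 and 135.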

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

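The fits on libraries 1 and 2 alone, with library 3 as a batch term, with the library total together with the replicate block, with the first row of each sequence, and the stricter pairing of arms, were chosen after the data were seen; the other alternatives were planned. The miR-430 list stayed lower under each of its 12 alternatives, and its share of the library differed by -93.2 to -87.0 percentage points when 1 library was left out. Shares of the other lists, totals, numbers of features and arms also kept their side of the threshold, which 3 against 3 libraries cannot pass for shares, totals and numbers of features; the share difference of the miR-17/92 clusters ran from -0.657 to 1.51 percentage points and that of the family of miR-130, miR-301 and miR-454 from -0.0136 to 0.0803 when 1 library was left out. The share of the miRNAs that bypass the Microprocessor gave no value with zebrafish names alone. The cause of the changes below was not tested, except where the alternative has fewer samples or features. The upward shift with library totals is also excepted, since it follows from the share of miR-430 in the totals, as stated above.

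Against 11 lower features, the count was 17 with DESeq2 size factors, 0 with library totals, 25 without scaling, 64 scaled to predicted hairpins, 39 scaled to the total without miR-430, 31 with the DESeq2 Wald test (608 adjusted p were NA), 20 with limma-voom, 51 with limma on normalized values (52 with either other pseudocount), 19 without a filter, 20 with at least 10 reads in 3 libraries, 36 with rows kept apart and 17 with the first row only. It was 4 with the replicate block, 79 in libraries 1 and 2 alone, 28 with library 3 as a batch term, and 0 to 11 when 1 library was left out. The scaling to predicted hairpins rested heavily on PC-5p-27_64448 in libraries 1 and 2, as stated above. Against 0 higher features, the count was 2 with library totals, 2 with the DESeq2 Wald test, and 1 with limma-voom, each limma fit on normalized values, no filter or rows kept apart. It was 16 in libraries 1 and 2 alone, 5 with the batch term, 87 with library totals and the block together, and 0 each time 1 library was left out.

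Among lists, the miR-17/92 call ended with an estimated correlation (adjusted p = 0.324). New calls were the miR-15/16 family and the epithelial list without a filter (camera adjusted p = 0.0441 and 0.0129). The let-7 family was called with the replicate block (0.0342) and without MZdgcr8 library 2 or 3 (0.0344 to 0.72 over the 6 left-out libraries). These calls used the preset correlation. With an estimated correlation and the main filter, each of these lists was at 0.914. The block changed no other list call. Among classes, calls ended with an estimated correlation for zebrafish names (0.236), other species (0.48), predicted hairpins (0.236) and sequences outside the genome (0.48). Fry asks another question, whether a set changes at all in 1 direction, so it neither ends nor adds a call of a difference from the other features; it gave 0.135, 0.781, 0.781 and 0.781 for these classes and 0.0400 for the sensory list. Predicted hairpins lost the call with library totals (0.0839). Other species and sequences outside the genome lost it without a filter (0.655 and 0.357), and ranged from 1.78e-05 to 0.54 and from 0.00028 to 0.54 when 1 library was left out.

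Of 49 named features that were tested, 11 were called. Of the 27 alternatives, each of these was tested under at least 24, and 7 under all 27; none changed direction in those fits, and none kept its call in all of them. Of the other 38, 31 changed direction and 29 were called under at least 1 alternative. MiR-100-5p was called higher, at 3.44, with library totals and the block together, where the median of all tested features was 4.12. In data simulated at the TMM effective sizes, 0 of 18 tested features with a 32-fold change were called at the spread of these libraries. At a dispersion of 0.1, all 34 were called, so the spread alone can cause such a loss. Whether depth adds to the loss was not tested, since the simulated mutant libraries were deeper than the real ones and depth was not varied. Depth limits values at 0, which are known only as below 5 reads, in MZdgcr8 library 3 out of 5791.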

Other observations

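All tests in this part were chosen after the results they bear on had been seen. In libraries 1 and 2 alone, 79 features were lower in MZdgcr8, of which 57 had zebrafish names, 7 had names of other species and 15 were predicted hairpins; 16 were higher, of which 15 were predicted hairpins. The lower ones, named here after their values were seen, included 14 of 20 tested members of the miR-17/92 clusters, 5 of 9 of the miR-15/16 family, 6 of 11 of the epithelial list and all 9 of the miR-430 list, against 79 of 262 features in all. As lists, miR-17/92 and miR-430 passed in this fit with the preset correlation (camera adjusted p = 4.04e-05 and 3.92e-05). The miR-15/16 family and the epithelial list did not (camera adjusted p = 0.279 and 0.27). An estimated correlation was used over all 6 libraries only, where miR-17/92 did not pass and miR-430 did (camera adjusted p = 0.324 and 0.0287). Lower members numbered 3 of 9 in the neural list, 3 of 11 in the miR-10 group, 6 of 35 in the widely expressed list, 0 of 14 in let-7 and 0 of 5 in the mesenchymal list. MiR-92a-3p had a log2 fold change of -4.49 (SE 0.459, adjusted p = 0.0102, edgeR, 2 against 2 libraries), with 41094 and 47182 raw reads in wild type and 706 and 2586 in MZdgcr8. The fish miRNAs miR-724 and miR-725-5p were also among them, and were at 0 in all 3 mutant libraries, at least 14.5-fold and 16.4-fold lower over the 6 libraries. The tissue miRNA miR-122 held 133 raw reads in MZdgcr8 library 2 and at most 5 in any other library.

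Of the 10 ways to split the 6 libraries into 3 and 3, only the real split gave as many called features, 11, and the highest other gave 0; the splits are too few for a share under 0.05. The real split is also among those that part each same-numbered pair, and the others of that kind gave 0.

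Many zebrafish-named miRNAs outside the miR-430 family kept reads in MZdgcr8. A candidate explanation is RNA of a mammal in the libraries, which would add reads to sequences shared by fish and mammals. Sequences that the table ties to a mammal hairpin had a median log2 fold change of 0.46 (29 sequences) against -1.32 for the other 57. The difference was 1.78 (permutation within wild-type abundance classes, p = 0.0164), and 1.87 in libraries 1 and 2 alone (same permutation, p = 0.0814). The permutation took sequences as units, though related sequences can share reads, so its p does not measure the spread between libraries. With TMM, 17 of the 29 and 19 of the 57 had a log2 fold change above 0, and the table's list of mammal hairpins may be incomplete, so how much of the pattern this could account for was not settled. Scaling stays open too, because the median of these miRNAs ran from -3.61 to 3.74 over the 6 scalings, as do processing that does not need Dgcr8 and maternal or older RNA that persisted, which were not tested.

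Reads of miR-430 left in the mutant libraries could come from carry-over, which from these wild-type libraries as the whole source would keep their ratio of miR-430c-3p to miR-430a-3p, 0.103 to 0.181. In MZdgcr8 the upper 95% counting limit of that ratio was 0.0826 over the 3 libraries, with libraries at 0 set to 5 reads (24 against 438 reads), which argues against it; it was 0.0806 in libraries 2 and 3 each, while library 1, at 0.0986 with a limit of 0.171, overlapped wild type. The ratio of miR-430a-12-5p to miR-430a-3p, 0.00392 to 0.17 in wild type, was 0.472 and 1.16 in MZdgcr8 libraries 1 and 2 (lower limits 0.347 and 0.922), but 0.0946 in library 3, inside that range. The ratio of miR-430b-3p to miR-430a-3p was 2.387 and 5.122 in MZdgcr8 libraries 1 and 2, against 1.067 and 1.085 in wild-type libraries 1 and 2. In MZdgcr8 library 3 it was 4.20, near that of wild-type library 3 alone (4.46). The miR-430a-12-5p ratio of wild-type library 3, 0.00392, was below the lower limit of 0.0505 in MZdgcr8 library 3. Carry-over as part of the reads, carry-over from libraries not analysed here, and a low level of processing in the mutants, stay open.

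The number 3 libraries stood apart from libraries 1 and 2 in both groups. Depth is not a likely cause of the whole difference, although wild-type library 3 held only 34118 reads outside miR-430: 19 of 94 features with at least 100 reads in wild-type libraries 1 and 2 were at 0 in it, where that depth gives at least 29.4 reads each. In both number 3 libraries and in no other, 25 features were seen, against at most 15 for any other pair of a wild-type and a mutant library, which restates the pattern and does not tell its source. A difference between library batches, which the labels do not name, and one between clutches or collection days cannot be told apart here.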
